A study of Mus musculus with 4 samples.

How the data were processed

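Total RNA was extracted with Trizol from mouse hearts, and libraries were made by a standard Illumina protocol, per the labels' protocols. TopHat2 2.0.13, Cufflinks 2.1.1 and the mm10 build are listed in the submitters' processing notes, and the annotation release and the mapping settings are not given in the sources used here. The authors deposited FPKM values per gene, in a file for each library and in a series-wide table with a column per library, and both sources held the same set of values for each gene and library. FPKM is already scaled per kilobase and to the mapped fragments of the library by the authors, and no further scaling between libraries is recorded. A quantile-normalized FPKM table was also deposited by the authors and was not used in the tests. The comparison table holds, per the file headers, FPKM per condition, log2 fold changes, a statistic, p-values and q-values from cuffdiff 2.1.1 with default settings. Selection flags, deposited as scores of 0 or 1, and the hit counts and p-values of the authors' enrichment tables were used only to describe the authors' lists. Infinite or unreadable log2 fold changes of the deposited table were left out.

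The 4 libraries were grouped by the genotype in the labels into 2 control and 2 Tbx20_OE libraries, each from a heart of its own per the labels' protocols. The low FPKM values showed no steps from whole reads: at most 0.51% of genes below 0.3 FPKM in a pair of libraries shared a ratio, within 0.002 on the log2 scale. Depth is therefore unknown, and counting error cannot be given. The 4 genes with a failed estimate, all listed at 0 in the libraries concerned, were left out of the tests, and 1 further gene of the series-wide table, not matched in the files per library, was not used here. Of symbols at several loci the entry with the highest mean was used, and for 2 symbols, Hba-a1 and Hba-a2, the series-wide table joined different loci in different libraries. File positions are given with 1 added to the start, because 11412 of 21864 compared loci then matched a transcript start of GENCODE M21, against 1042 as given.

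Values were analysed as log2(FPKM + 1), with a pseudocount of 1, for the 10513 genes with a mean FPKM of at least 1 over the 4 libraries. The limma 3.58.1 moderated test with a mean-variance trend was run in R 4.3.3, with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 35 gene lists held 738 distinct genes, of which 536 were tested. Lists with at least 5 measured members, 31 in all, were tested by camera with a preset correlation of 0.01, and camera with an estimated correlation and fry were run beside it. With an estimated correlation camera relies on the residual degrees of freedom, 2 here and fewer with a library left out. It then has little power after adjustment over the lists, so a call lost that way does not by itself count against a list. fry's p tests whether a list moves one way on balance and its mixed p whether members change either way. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were named as follows: Tbx20; the measured genes of the list linked to Tbx20; up to 12 each way among separated genes passing the test, ordered by fold change and filled by smallest unadjusted p at 1.5-fold or more; up to 4 members of each list described; and the 10 largest changes each way that the authors' table calls significant, of which 1 was higher. Predicted genes and Rik, Gm-numbered, Mir and Snor genes were left out of the 24 and counted. Snord33 is named because it is 1 of 2 genes called. Sln, Cfd, S100a9, Atf3, Nr4a3, Ppargc1a, Rpl13a, Myh6, Cyr61, Snora16a and Hbb-bs were chosen after their values were seen.

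The limma test was checked on simulated data for all 10513 genes, 50 of them changed at each of 4 sizes. Means were the real ones, and spreads were those moderated by limma rather than each gene's own. The limma test called 34% of genes changed 2-fold and 98% of those changed 4-fold, and 8 of 10313 unchanged genes. In a second simulation camera called the 1 list that had been changed and 1 of the other lists. In both simulations genes varied independently with normal noise, and no library stood apart from the others. The real libraries differ in this, so these rates may not hold for them. Transcript length and GC content came from the longest GENCODE M21 transcript of each symbol, which 95.4% of tested genes had. Alternatives covered the pseudocount, the filter, the scaling, the source of the FPKM values, the limma settings, the threshold, a replicate block and each library left out. A crossed block and GC-corrected values, in 10 GC bins per library, were chosen after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.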

Results

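Gene expression was measured by RNA sequencing of total RNA from the hearts of mice aged 12 weeks. Overexpression of Tbx20, a T-box transcription factor of the heart, had been induced in cardiomyocytes at 8 weeks of age, 4 weeks before the hearts were taken. The control hearts carried the tamoxifen-regulated Cre recombinase driven by the alpha myosin heavy chain promoter. The overexpressing hearts, named Tbx20_OE here, carried the same Cre together with the inducible Tbx20 transgene. Each group held 2 libraries, each from a heart of its own per the labels' protocols. The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), so the number of reads behind them is unknown, and their sum over genes lay between 453197 and 513334 per library. The comparison asks which transcripts of the adult heart differ after 4 weeks of Tbx20 overexpression. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and the limma test covered 10513 genes with a mean FPKM of at least 1.

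Tbx20, on chromosome 9 from 24720812 to 24774303 of mm10, was measured at 6.99 and 4.58 FPKM in the control libraries and at 11.03 and 16.4 FPKM in the Tbx20_OE libraries. Its mean was 5.78 ± 1.70 FPKM in control (SD, n = 2) and 13.7 ± 3.76 FPKM in Tbx20_OE (SD, n = 2). The Tbx20 log2 fold change was 1.11 with a standard error of 0.30, which is 2.17-fold, and both Tbx20_OE libraries lay above both control libraries. The difference did not pass adjustment over all genes (limma, Benjamini-Hochberg adjusted p = 0.848). It passed without control replicate 1 (log2 1.37, adjusted p = 0.0271), where the lone control library is assumed to vary like the other group, and not with any of the other 3 libraries left out (adjusted p from 0.862 to 1). An exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.333.

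Immediate early genes, which cells switch on within minutes of a stimulus, had lower values in the Tbx20_OE hearts. For 13 of 26 measured members both Tbx20_OE libraries lay below both control libraries. Over all 10513 tested genes the same held for 501. Fos, a subunit of the AP-1 transcription factor, was at 53.2 and 18.1 FPKM in control and at 0.808 and 0.412 FPKM in Tbx20_OE, a log2 fold change of -4.33 with a standard error of 0.50. Egr1, a zinc finger transcription factor, was at 129 and 26.5 FPKM in control and at 2.05 and 2.07 FPKM in Tbx20_OE (log2 -4.29, standard error 0.70). In all, 24 of the 26 members had a negative fold change, and the median log2 fold change was -0.74, and -1.23 without Tbx20_OE replicate 2. Over all 4 libraries, with the group as the only term, no member passed the limma test adjusted over all genes, and Fos came closest (adjusted p = 0.441). With a replicate block added Fos and Egr1 passed, though same-numbered libraries are not shown to be pairs. Adjusted over the list alone, 9 members were lower, namely Fos, Jun, Junb, Egr1, Ier2, Dusp1, Zfp36, Klf2 and Cyr61. The camera test called the list lower in Tbx20_OE (Benjamini-Hochberg adjusted p = 2.16e-28 with the preset correlation of 0.01). With an estimated correlation the adjusted p = 0.884, and the unadjusted p = 0.0300. That form of the test relies on 2 residual degrees of freedom and has little power here.

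Without control replicate 2, 16 genes were lower in Tbx20_OE at adjusted p under 0.05, and 9 of those 16 were immediate early genes. Without control replicate 1, 1433 genes were called in either direction. In each of these fits the lone control library is assumed to vary like the Tbx20_OE libraries, and both use the same Tbx20_OE libraries. Fos had a limma adjusted p = 7.38e-05 without control replicate 2, 0.000339 without control replicate 1, 0.0297 without Tbx20_OE replicate 1 and 0.0951 without Tbx20_OE replicate 2. Jun, the partner of Fos in AP-1, was nearly equal in the controls at 39.3 and 38.6 FPKM and lay at 14.8 and 12.2 FPKM in Tbx20_OE. Dusp1, a phosphatase that turns off MAP kinases, was at 122 and 64.1 FPKM in control and at 24.1 and 19.2 FPKM in Tbx20_OE. Klf2, an endothelial transcription factor responsive to blood flow, was at 80.0 and 64.0 FPKM in control and at 31.5 and 23.1 FPKM in Tbx20_OE. The fold change of 2 members was positive. One was the nuclear receptor gene Nr4a3, at 10.9 FPKM in Tbx20_OE replicate 2 and below 1 FPKM in the other 3 libraries, and it passed without Tbx20_OE replicate 1 (log2 3.19, limma adjusted p = 0.0127), where replicate 2 is the lone Tbx20_OE library.

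**Figure D1:**
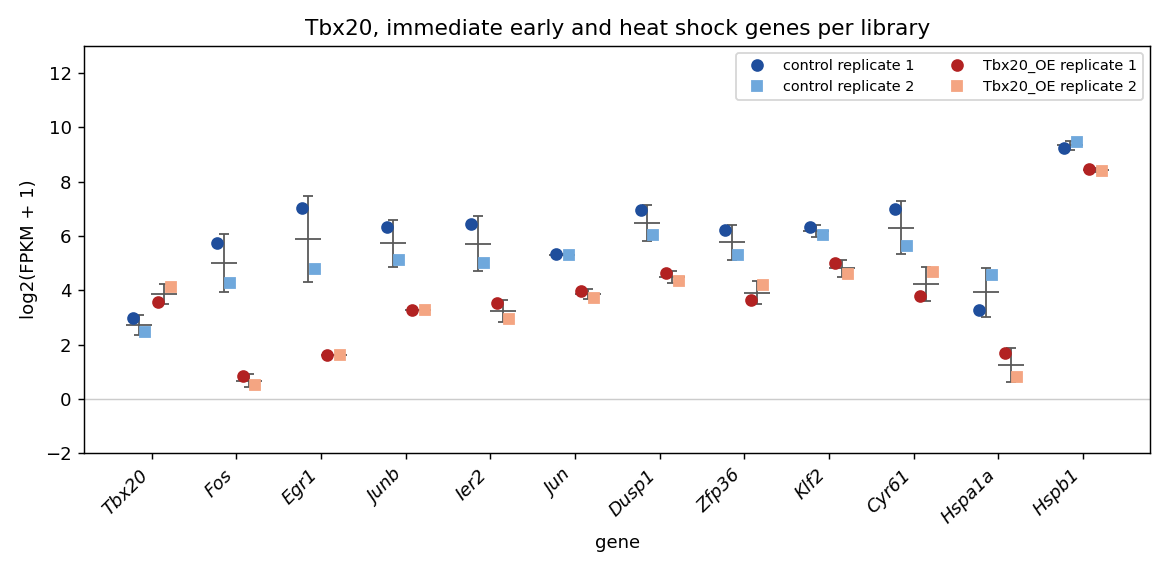
Expression as log2(FPKM + 1) of Tbx20, 9 immediate early genes and 2 heat shock genes in each library, with points for the libraries and grey bars for the group mean and SD (n = 2). Fos lies at 53.2 and 18.1 FPKM in the control libraries and below 1 FPKM in both Tbx20_OE libraries.

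Heat shock and unfolded protein response genes had lower values too. Of 26 measured members, 21 had a lower mean in Tbx20_OE and 9 had separated groups, with a median log2 fold change of -0.28. The median was -0.45 without control replicate 2, -0.15 without Tbx20_OE replicate 2, -0.44 after median centring, -0.43 with quantile normalization and -0.45 with GC-corrected values. Hspa1a, a stress-inducible chaperone, was at 8.74 and 22.8 FPKM in control and at 2.24 and 0.756 FPKM in Tbx20_OE (log2 -2.67, standard error 0.51). Hspa1b, its neighbour and near-identical copy, was at 4.91 and 18.8 FPKM against 2.11 and 0.534 FPKM, so the division of reads between these copies is uncertain. Hspb1, a small heat shock protein abundant in muscle, was at 652 ± 73.6 FPKM in control and 345 ± 16.7 FPKM in Tbx20_OE (SD, n = 2). Sdf2l1, an endoplasmic reticulum chaperone component, was at 10.5 ± 1.79 FPKM and 4.85 ± 1.88 FPKM (SD, n = 2). No member passed over all genes, and 0 passed when adjusted over the list alone. Without control replicate 1, Hspa1a, Hspa1b and Sdf2l1 passed over all genes (limma adjusted p = 0.00516, 0.00847 and 0.0430), in a fit whose lone control library is control replicate 2. None of these 3 genes passed without control replicate 2 (adjusted p = 0.172, 0.608 and 1). Camera called the list lower (adjusted p = 6.02e-14 with the preset correlation; adjusted p = 0.884 with an estimated correlation).

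Over all genes, 2 were higher and 0 lower at a limma adjusted p under 0.05, against 111 higher and 49 lower at an unadjusted p under 0.05. Those 160 compare with 526 that chance would give. Both called genes carry limits. Hba-a1, an alpha globin gene, was at 0.00712 and 0.290 FPKM in the control rows and at 254 and 155 FPKM in the Tbx20_OE rows of the series-wide table. With values joined by locus, control replicate 2 held 106 FPKM at the same copy as the Tbx20_OE values, and the call ended (log2 4.26, adjusted p = 0.848). The small nucleolar RNA Snord33 lies inside Rpl13a, on chromosome 7 from 45126864 to 45126945. It was listed at 0 in both control libraries and at 1282 and 1031 FPKM in Tbx20_OE (limma adjusted p = 0.000385), while its host Rpl13a was at 437 and 770 FPKM in control and at 532 and 383 FPKM in Tbx20_OE. The authors' deposited comparison gave Snord33 0 FPKM in control and 1993.5 FPKM in Tbx20_OE, and did not call it (cuffdiff q = 0.906).

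Counted by size, 29 separated genes were at least 2-fold higher and 26 at least 2-fold lower in Tbx20_OE. Groups of 2 separate by chance for 33.3% of unchanged genes, and 32.8% of the tested genes were separated here. That total hides a one-way shift. Of the separated genes 2950 were higher and 501 lower in Tbx20_OE, where chance would favour neither direction. The median log2 fold change of all tested genes was 0.149, and median centring moved the values by 0.161. With that shift removed, the split was 15 higher against 43 lower, and with quantile normalization 15 against 40.

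Other genes were named by smallest unadjusted p among separated genes with at least 1.5-fold change. Apart from Hba-a1, none of these passed adjustment over all genes (limma adjusted p from 0.438 to 0.848). Ankrd1, a sarcomere-associated stress response gene, was at 202 ± 53.7 FPKM in control and 551 ± 193 FPKM in Tbx20_OE (SD, n = 2). Ucp3, a mitochondrial uncoupling protein gene of muscle, was at 5.44 ± 0.725 FPKM and 11.2 ± 0.0236 FPKM (SD, n = 2). Gadd45a, a growth arrest and DNA damage gene, was at 5.87 ± 0.901 FPKM and 11.5 ± 1.19 FPKM, and Rbm3, a cold-inducible RNA-binding protein gene, at 22.2 ± 3.19 FPKM and 44.95 ± 8.56 FPKM (SD, n = 2). Prune2, Ccl12, Atcayos, H2-T22, Msmp and Amd2 had fold changes between 1.66 and 3.42. Values of Amd2 and H2-T22 are uncertain because closely similar genes share reads with them, and those of Atcayos because it is antisense to Atcay and no strand setting is given in the sources used here. The pseudogene Apoo-ps was at 57.5 and 16.6 FPKM in Tbx20_OE and listed near 0 in control, and as a pseudogene it can share reads with its parent gene. Leaving out either control library did not change the log2 fold change of Apoo-ps. Fits without a Tbx20_OE library cannot show whether its difference is stable, because its spread then comes only from control values near 0. The authors' deposited comparison left Apoo-ps untested, at 0 FPKM in control and 112 FPKM in Tbx20_OE. On the lower side, besides the immediate early and heat shock genes, Ptgfr, the prostaglandin F receptor gene, was at 2.43 ± 0.288 FPKM in control and 0.876 ± 0.0673 FPKM in Tbx20_OE (SD, n = 2). Sbk2, a kinase gene, was at 2.33 ± 0.887 FPKM and 0.558 ± 0.0170 FPKM (SD, n = 2). Rnaset2b was at 5.94 ± 3.63 FPKM and 1.12 ± 0.0196 FPKM (SD, n = 2), with reads that its near-identical copy Rnaset2a can share. In the authors' deposited comparison Rnaset2b went the other way, at 4.21 FPKM in control and 4.68 FPKM in Tbx20_OE. Amd2 was nearly equal there, at 68.6 FPKM in control and 72.3 FPKM in Tbx20_OE. Apart from Hba-a1, each of these genes but Amd2 passed over all genes without control replicate 1 (adjusted p from 0.00274 for Rnaset2b to 0.0481 for Ccl12, and 0.0507 for Amd2), in a fit whose lone control library is control replicate 2. Of these genes Apoo-ps alone passed without control replicate 2, and the others had adjusted p from 0.0731 for Amd2 to 0.902 for Ankrd1. A further 25 predicted or small RNA genes were separated with at least 1.5-fold change.

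Control replicate 2 stood apart from the other 3 libraries. Its Pearson correlation with them on the log2 scale was between 0.927 and 0.957, against 0.981 to 0.982 among the others, and the first principal component, with 72.4% of the variance, separated it from them. It held 86 genes at least 2-fold above and 328 at least 2-fold below all the other libraries, while no other library exceeded 20 in either direction. Its expression followed GC content (Spearman rho of 0.45 across genes with the deviation from the mean of the 4 libraries), with rho of -0.38 in Tbx20_OE replicate 2. Genes are not independent replicates, so these are descriptions across genes.

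**Figure D2:**
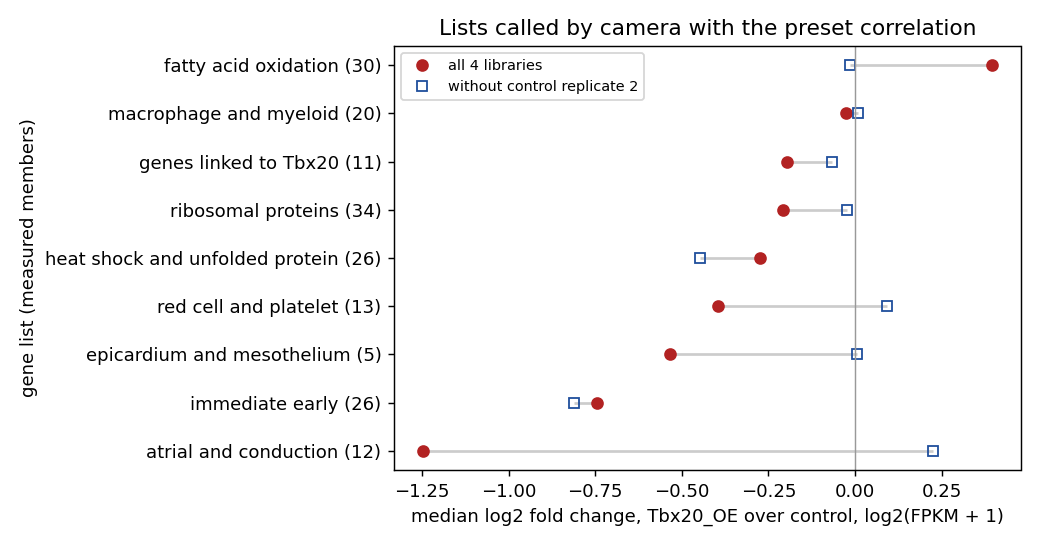
Median log2 fold change of Tbx20_OE over control for the 9 gene lists called by camera, over all 4 libraries (filled circles) and without control replicate 2 (open squares), with measured members in parentheses. The immediate early list lies at -0.74 with and -0.81 without that library, and the atrial list at -1.25 with and 0.22 without it.

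Markers of atrial muscle were abundant in control replicate 2 and low in the other 3 libraries. Myl7, the atrial regulatory myosin light chain, was at 958 FPKM there and at 0.0536, 4.77 and 0.107 FPKM in control replicate 1 and the Tbx20_OE libraries. Myl4, the atrial essential light chain, was at 605 FPKM there and at most 4.30 FPKM elsewhere, and Mybphl, a myosin-binding protein of atrium and conduction system, at 69.4 FPKM and at most 0.267 FPKM. Nppa, which encodes atrial natriuretic peptide, was at 1452 FPKM there and between 126 and 228 FPKM elsewhere. Stard10 was at 57.3 FPKM there and at most 15.02 FPKM elsewhere, while Nr2f2, a transcription factor of atrial and venous cells, was at 2.44 and 2.25 FPKM in control against 1.90 and 1.48 FPKM. Of 12 measured members of the atrial and conduction list, 9 were highest in control replicate 2, and 0 passed the limma test over all genes or adjusted over the list alone. Camera called the list lower in Tbx20_OE (median log2 -1.25, adjusted p = 2.78e-06; adjusted p = 0.884 with an estimated correlation). Without control replicate 2 the median was 0.22, and the call ended (adjusted p = 0.795).

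Other tissue markers were high in that library too. Msln and Upk3b, markers of the mesothelial layer, were at 10.97 and 9.52 FPKM in control replicate 2 and at most 0.250 FPKM elsewhere. The epicardium and mesothelium list of 5 measured genes was called lower by camera (adjusted p = 0.00525; adjusted p = 0.884 with an estimated correlation), and 0 members passed adjusted over the list alone. Aldh1a2, a retinoic acid synthesis gene, was at 3.69 FPKM there and at most 1.25 FPKM elsewhere, and Sulf1 had a log2 fold change of 0.21. The red cell and platelet list was called lower by the same adjusted p of 0.00525, again 0.884 with an estimated correlation, with 11 of its 13 members highest in control replicate 2. Ppbp, a platelet chemokine gene, was at 26.2 FPKM there and at most 1.56 FPKM elsewhere. The median log2 fold change of the list was -0.40 and its mean -0.07. Hba-a1 alone passed adjusted over the list alone, and fry's test of change in either direction gave an adjusted p = 0.0134. Both results used the series-wide values of Hba-a1, and with values joined by locus 0 members passed adjusted over the list alone (0.366 for Hba-a1) and fry's adjusted p was 0.829. Levels of single globin genes are uncertain because near-identical copies share reads. Hbb-b1, for example, was at 0.000707 FPKM in control replicate 2, where the overlapping Hbb-bs was at 1161 FPKM. The macrophage and myeloid list had a median log2 fold change of -0.03, with 8 of 20 members higher and 12 lower, and 0 passed adjusted over the list alone. Cd14, a lipopolysaccharide receptor gene, was at 12.4 ± 0.155 FPKM in control and 7.52 ± 2.52 FPKM in Tbx20_OE (SD, n = 2). Camera called the list lower (adjusted p = 0.00922; adjusted p = 0.884 with an estimated correlation). Without control replicate 2 these calls ended (adjusted p = 0.783 for epicardium and mesothelium, 0.115 for red cell and platelet, 0.795 for macrophage and myeloid), and the medians, below 0 over all libraries, were 0.0051, 0.093 and 0.0074. Without Tbx20_OE replicate 2 the red cell and platelet median was 0.018. The red cell and platelet call also ended after median centring (median -0.56, adjusted p = 0.281) and with quantile normalization (median -0.57, adjusted p = 0.200). It ended too with GC-corrected values (median -0.61, adjusted p = 0.211) and at a mean FPKM of at least 5 (median -0.39, adjusted p = 0.272). Without Tbx20_OE replicate 2 the macrophage and myeloid median was 0.26. The macrophage and myeloid call also ended with GC-corrected values (median -0.15, adjusted p = 0.0560) and with no filter on low values (median 0.0026, adjusted p = 0.220).

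**Figure D3:**
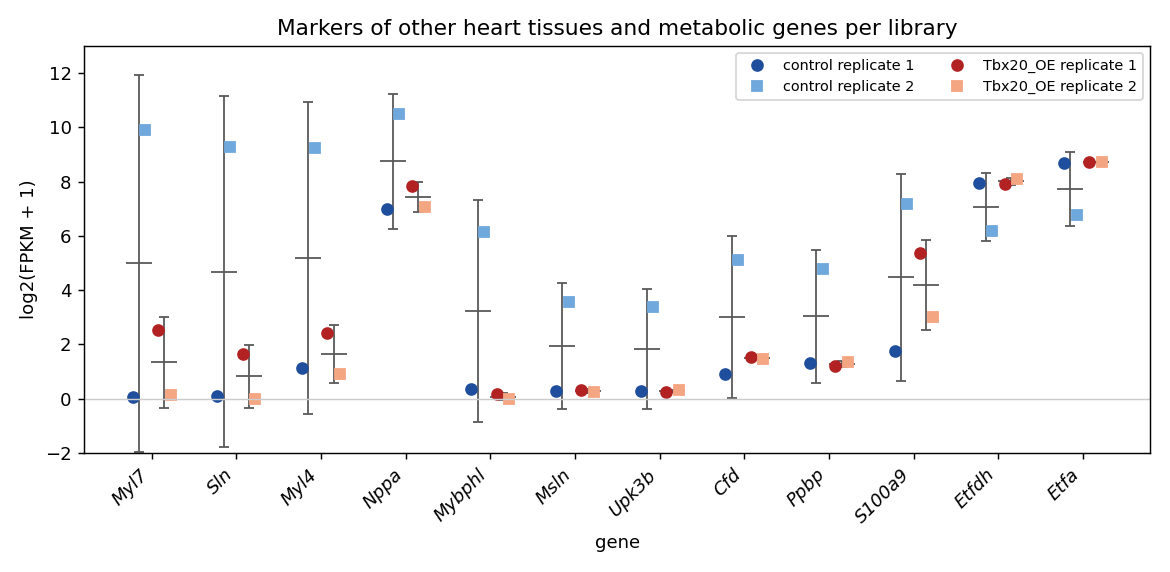
Expression as log2(FPKM + 1) of 5 atrial genes, 2 mesothelial genes, Cfd, Ppbp, S100a9 and 2 fatty acid oxidation genes in each library, with points for the libraries and grey bars for the group mean and SD (n = 2). Myl7 lies at 958 FPKM in control replicate 2 and at most 4.77 FPKM in the other libraries, and Etfa at 107 FPKM there and at 411 FPKM or more elsewhere.

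Fatty acid oxidation genes, which serve the main fuel of the adult heart, had higher means in Tbx20_OE for 28 of 30 measured members, with a median log2 fold change of 0.40. Of these 30, 25 were lowest in control replicate 2. Etfa and Etfdh, which pass electrons from fatty acid oxidation to the respiratory chain, were at 411 and 247 FPKM in control replicate 1, at 107 and 71.7 FPKM in control replicate 2 and between 240 and 422 FPKM in the Tbx20_OE libraries. Plin2, a lipid droplet coat protein gene, was at 17.3 ± 4.16 FPKM in control and 24.6 ± 1.34 FPKM in Tbx20_OE (SD, n = 2), and with Ucp3 it was among the 11 separated members. Over all 10513 tested genes, 2950 were separated higher. None of the fatty acid oxidation genes passed over all genes or adjusted over the list alone. Camera called the list higher (adjusted p = 0.0239; adjusted p = 0.919 with an estimated correlation). Without control replicate 2 the median was -0.01 and the call ended (adjusted p = 0.489), and after median centring the median was 0.23.

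Ribosomal protein genes had lower means in Tbx20_OE for 27 of 34 members, with a median log2 fold change of -0.21, and 27 of the 34 were highest in control replicate 2. Rps2 was at 1128 and 1681 FPKM in control and at 1181 and 892 FPKM in Tbx20_OE, and Rps18, Rps19 and Rpl27 were ordered alike. No member passed over all genes or adjusted over the list alone. Camera called the list lower (adjusted p = 4.23e-08; adjusted p = 0.884 with an estimated correlation). Without control replicate 2 the median was -0.02 and the call ended, and without Tbx20_OE replicate 2 the median was -0.017. It was -0.40 without Tbx20_OE replicate 1, -0.38 without control replicate 1 and -0.37 after median centring.

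A list of genes linked to Tbx20 in earlier work on this transgene was tested. That work may have used these samples, so the list is not independent evidence of its direction. Of 11 measured members, 4 had higher and 7 lower means in Tbx20_OE, 0 passed over all genes, and 0 passed adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, was at 8.07 and 27.0 FPKM in control and at 10.2 and 16.3 FPKM in Tbx20_OE. Meis1, a homeobox gene that restrains cardiomyocyte division, was at 3.36 ± 0.219 FPKM in control and 4.25 ± 0.196 FPKM in Tbx20_OE (SD, n = 2). Btg2, an antiproliferative gene that is also an immediate early gene, was at 81.4 and 12.1 FPKM in control and at 7.02 and 14.2 FPKM in Tbx20_OE, and it passed without control replicate 2 (log2 -2.90, adjusted p = 0.0312) and not without control replicate 1 (log2 -0.25, adjusted p = 0.642). Tbx5 was at 3.28 ± 0.709 FPKM and 2.34 ± 0.376 FPKM, and Gja5, a connexin of atrium and conduction system, at 3.12 ± 1.62 FPKM and 1.95 ± 1.11 FPKM (SD, n = 2). Ctnnb1, Cacna1c, Igf1, Akt1 and Tbx2 had log2 fold changes between -0.32 and 0.57. Bmp2 and Mycn lay below the limit for testing, at means of 0.284 and 0.710 FPKM, and Bmp10 was listed at 0 in all libraries. Camera called the list lower (adjusted p = 0.0239; adjusted p = 0.884 with an estimated correlation), and the call ended without control replicate 2 (adjusted p = 0.291) and without Tbx20_OE replicate 1 (0.0572). Over all libraries as deposited the median log2 fold change of the list was -0.20. The call also ended after median centring (median -0.36, adjusted p = 0.124), with quantile normalization (-0.37, 0.112) and with GC-corrected values (-0.25, 0.160). It ended too with no filter on low values (median -0.20, adjusted p = 0.0619) and at a mean FPKM of at least 5 (-0.034, 0.272).

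The other 22 of the 31 lists tested gave camera adjusted p from 0.267 to 0.973. Of 10 measured cell cycle genes, 8 had higher means in Tbx20_OE, with none past the test over all genes or adjusted over the list alone. Ccnd1, which encodes cyclin D1, was at 6.39 ± 2.64 FPKM in control and 11.6 ± 0.761 FPKM in Tbx20_OE (SD, n = 2), a log2 fold change of 0.82 (limma adjusted p = 0.848), and Pcna, a DNA replication clamp gene, was at 19.9 ± 5.91 FPKM and 29.1 ± 0.524 FPKM (SD, n = 2).

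The authors' deposited table compared the groups with cuffdiff and gives an FPKM value per condition. It tested 12850 of 24327 entries and called 31 significant, 1 higher and 30 lower in Tbx20_OE. In the authors' deposited table, Tbx20 had 9.31 FPKM in control and 18.8 FPKM in Tbx20_OE, a log2 fold change of 1.01 with q = 0.911. Both values lay above those of the group's libraries (6.99 and 4.58 FPKM in control, 11.03 and 16.4 FPKM in Tbx20_OE). They are therefore not means of the FPKM per library. The gene called higher there, Pttg1, had 9.29 and 45.8 FPKM in the authors' deposited table, while the libraries were at 4.99 and 6.25 FPKM in control and at 6.86 and 54.5 FPKM in Tbx20_OE. The largest decreases that the authors' deposited table calls significant were of Myl7 (log2 -7.65), Myl4 (-6.89), Fos (-5.98), Egr1 (-5.32), Sbk3 (-4.81), Msln (-4.78), Ppbp (-3.72), Hspa1a (-3.29), Itga2b (-3.21) and Dkk3 (-3.15), each with q = 0.0222. Of these 10, Fos, Egr1, Hspa1a and Sbk3 had both control libraries above both Tbx20_OE libraries, with Sbk3 at 0.809 FPKM in control replicate 1 and 11.4 FPKM in control replicate 2. Myl7, Myl4, Msln, Ppbp, Itga2b and Dkk3 had control replicate 1 within or below the range of the Tbx20_OE libraries and control replicate 2 above it. For Hba-a1 the authors' deposited table gave 1061 FPKM in control and 424 FPKM in Tbx20_OE, the opposite direction to the values per library in the series-wide table.

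In their deposited selection the authors marked 61 genes as up and 114 as down, by unadjusted p under 0.05, a log2 fold change beyond 0.5, an FPKM over 3 and a within-condition fold of at most 6. The cuffdiff q passed for 17 of these 175 genes. Of the 61 up genes, 58 were at least 0.5 log2 above control replicate 2 and 23 at least 0.5 above control replicate 1, with median differences of 1.22 and 0.43. Of 113 measured down genes, 81 were at least 0.5 log2 below control replicate 2 and 59 at least 0.5 below control replicate 1. In the authors' deposited enrichment table, 377 terms of the down list had q under 0.05, led by vasculature development (21 genes, q = 3.44e-08, with Jun, Junb, Egr1, Klf4, Nr4a1 and Cyr61 among them). No term of the up list did, and the smallest q was 0.109.

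**Figure D4:**
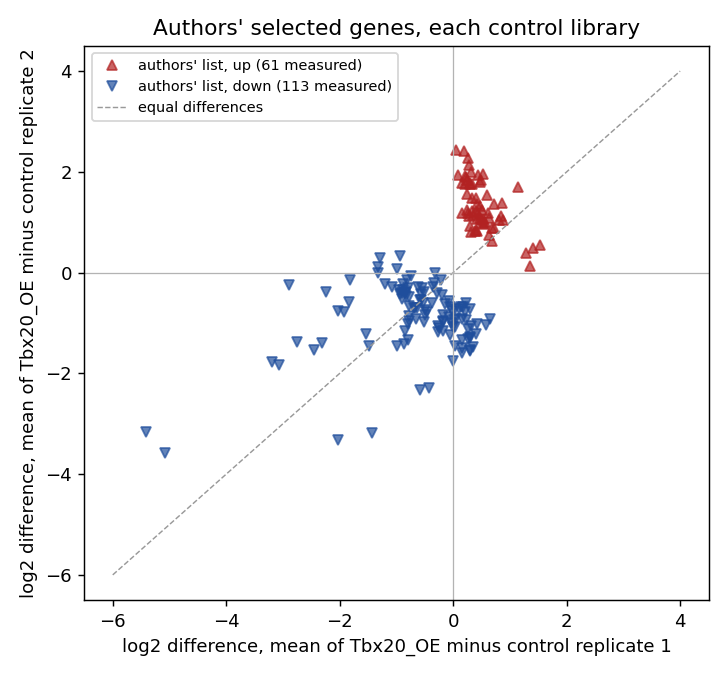
Log2 difference of the mean of the Tbx20_OE libraries from control replicate 1 (horizontal axis) and from control replicate 2 (vertical axis), on log2(FPKM + 1), for the 61 up and 113 down genes of the authors' selection that were measured. The up genes have a median difference of 0.43 from control replicate 1 and 1.22 from control replicate 2.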

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

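The crossed replicate block and the GC-corrected values were chosen after seeing the data, and the other alternatives before the data were examined. The Tbx20 log2 fold change stayed above 0 in each alternative, between 0.79 (pseudocount 5) and 1.38. With each library left out in turn it ran from 0.85 to 1.38, and its adjusted p was 0.0271 without control replicate 1 (log2 1.37) and between 0.0585 (crossed replicate block) and 1 in the other alternatives. The count of genes higher in Tbx20_OE, 2, was 1 with pseudocount 0.1, with no filter on low values and with values joined by locus, and 6 to 1195 with a library left out. The count of genes lower in Tbx20_OE, 0, was 0 to 238 with a library left out. The highest of these counts came without control replicate 1, where control replicate 2 is the lone control library and is assumed to vary like the other group. The separated genes at least 2-fold higher in Tbx20_OE, 29, were 80 with pseudocount 0.1, 10 with pseudocount 5, 15 with quantile normalization, 15 with median centring, 14 with GC-corrected values and 32 to 659 with a library left out. The separated genes at least 2-fold lower in Tbx20_OE, 26, were 17 with pseudocount 5, 40 with quantile normalization, 43 with median centring and 36 to 170 with a library left out. The gene lists called, 9, were 0 by camera with estimated correlation and 0 by fry, and 8 to 12 with a library left out, of which 2 were shared without control replicate 2. With GC-corrected values 9 lists were called, 6 of them shared. The members of fixed lists, adjusted over the list alone, were 11, and 11 to 136 with a library left out. The cause of these differences was not tested. Depth is unknown, so what it limits cannot be given.

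With the replicate block, 3 genes were higher (Apoo-ps, Hba-a1 and Snord33) and 3 lower (Fos, adjusted p = 0.00348, Egr1, 0.0289, and Snora16a), 10 lists were called, 13 members passed adjusted over the list alone, and the Tbx20 log2 fold change of 1.11 had an adjusted p of 0.999. Same-numbered libraries are not shown to be pairs, since their deviations correlated at -0.45 across genes. With the crossed replicate block, 12 genes were higher and 18 lower, 9 lists were called and 70 members passed adjusted over the list alone.

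With each library left out in turn, log2 fold changes (medians for lists) ran from below to above 0 for Aif1 (-0.076 to 0.57), Akt1 (-0.25 to 0.51), Aldh1a2 (-1.07 to 0.0051), Atf3 (-2.15 to 1.68), Cdkn1a (-1.01 to 0.62), Cfd (-3.61 to 0.60), Ctnnb1 (-0.093 to 1.23), Dkk3 (-2.96 to 0.58), Lgals3 (-1.04 to 0.31), Myl4 (-7.59 to 0.53), Myl7 (-8.57 to 1.26), Nppa (-3.06 to 0.45). They did so too for Nr4a3 (-0.19 to 3.19), Ppargc1a (-0.35 to 2.20), Rpl13a (-0.77 to 0.047), Rpl27 (-0.77 to 0.0024), S100a9 (-2.98 to 2.42), Sln (-8.44 to 0.72), Tbx2 (-0.18 to 0.12), Upk3b (-3.11 to 0.0087), the atrial list (-2.63 to 0.22), the epicardium and mesothelium list (-1.07 to 0.0051), the red cell and platelet list (-1.60 to 0.093), the fatty acid oxidation list (-0.015 to 0.75) and the macrophage list (-0.32 to 0.26). Median centring gave -0.033 for Akt1 and -0.059 for Myh6, pseudocount 5 gave 0.038 for Atf3, and GC-corrected values gave -0.014 for Meis1, -0.012 for Sulf1 and 0.022 for Tbx2, each opposite in sign to the value over all libraries as deposited. With a library left out, medians of the other called lists stayed below 0, at -1.23 to -0.51 for immediate early, -0.45 to -0.15 for heat shock, -0.40 to -0.017 for ribosomal protein and -0.25 to -0.050 for Tbx20-linked genes. At a mean FPKM of at least 5 the epicardium and mesothelium list held too few members to be tested. None of the genes named in this paragraph passed the limma test over all 4 libraries. The cause was not tested.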

Other observations

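Smooth muscle and fetal sarcomere genes were not called over all 4 libraries as deposited. With GC-corrected values camera with the preset correlation called the smooth muscle list (median log2 0.16, adjusted p = 0.0192). It then also called the antigen presentation (0.18, adjusted p = 0.0159) and glycolysis lists (0.21, adjusted p = 0.0315). Of 14 measured smooth muscle and pericyte genes, 11 had higher means in Tbx20_OE (camera adjusted p = 0.267; adjusted p = 0.884 with an estimated correlation). Tagln, an actin-binding protein gene of smooth muscle, was at 6.09 and 14.7 FPKM in control and at 28.5 and 19.2 FPKM in Tbx20_OE. Acta1, skeletal alpha actin, was at 148 and 291 FPKM in control and at 454 and 402 FPKM in Tbx20_OE, and Myh6, the adult cardiac myosin heavy chain, at 2187 ± 80.8 FPKM and 2351 ± 211 FPKM (SD, n = 2). The fetal sarcomere and stress list of 19 measured genes had a median log2 fold change of 0.16 and a mean of -0.37, and the median was 0.0036 after median centring, 0.018 with quantile normalization and -0.058 with GC-corrected values. Without control replicate 2, camera called the immediate early and heat shock lists and others that were not called over all libraries as deposited. Those higher in Tbx20_OE were smooth muscle (adjusted p = 0.000723), extracellular matrix (0.000347), fetal sarcomere (0.00305) and cell cycle (0.0243), with medians of 0.29, 0.25, 0.32 and 0.27. The endothelial and adrenergic hypertrophy lists were called lower relative to the other genes (adjusted p = 0.0437 and 0.0274), with medians of 0.03 and -0.01, and 6 endothelial members were separated each way. Those calls rest on a lone control library and on the preset correlation. None held with an estimated correlation, where the few residual degrees of freedom leave the test little power. With control replicate 1 left out instead, the smooth muscle, cell cycle, endothelial and adrenergic hypertrophy lists were not called. The extracellular matrix and fetal sarcomere lists were then called lower relative to the other genes. Their medians were -0.0031 and 0.076, against 0.21 for all tested genes. The fetal sarcomere list holds Myl7, Myl4, Mybphl and Nppa, atrial genes high in control replicate 2, the lone control library of that fit.

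Some genes were high in Tbx20_OE replicate 2 alone. Atf3, a stress-induced transcription factor gene, was at 48.3 FPKM there and at most 16.0 FPKM elsewhere. Ppargc1a, a regulator of mitochondrial biogenesis, was at 45.2 FPKM there and at most 11.1 FPKM elsewhere, and Pttg1, the securin gene of dividing cells, at 54.5 FPKM there and at most 6.86 FPKM elsewhere.

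Of the tests in the paragraphs that follow, median centring, quantile normalization, leaving out control replicate 1 and joining values by locus were alternatives fixed before the data were examined. They were set against these patterns only after the patterns were seen. The count of atrial genes, the Tbx20 level, the GC correction, the heat shock median and the count of unstable snoRNA estimates were chosen after the result was seen. Control replicate 2 stood apart from the other libraries. A swap with a Tbx20_OE library is argued against by its Tbx20 level of 4.58 FPKM, below both Tbx20_OE libraries. Atrial tissue in that library could account for part of the genes higher there, since 9 of 12 measured atrial and conduction genes were highest in it, with Myl7 at 958 FPKM and Sln at 613 FPKM. For the genes lower there a GC-linked bias is a candidate cause, since expression in that library followed GC content (Spearman rho of 0.45 across genes). After GC correction a new count over all genes gave 101 at least 2-fold below the other libraries, against 328 before. The count of genes higher there went from 86 to 126. That correction also removes a plain offset of the library, whose median log2(FPKM + 1) was 2.67, against 2.81 to 2.90 elsewhere. The drop therefore cannot separate GC content from that offset. Mesothelial and platelet genes were also high there (Msln at 10.97 FPKM, Ppbp at 26.2 FPKM). Of 9 measured adipocyte genes 4 were highest there, among them Cfd (33.5 FPKM, at most 1.90 FPKM elsewhere) and Adipoq (3.61 FPKM, at most 0.22 FPKM elsewhere). Another 4 were lowest there, among them Dgat2 (89.7 FPKM, at least 159 FPKM elsewhere). How each heart was dissected stays open.

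Immediate early genes had a median log2 fold change of -0.74. No member passed the limma test over all genes and all 4 libraries with the group as the only term. The camera call was lost with an estimated correlation (adjusted p = 0.884), where 2 residual degrees of freedom leave the test little power. Control replicate 1, the higher control for most of them, is argued against as the sole cause. Without it the median was -0.51 and 22 of 26 members were lower. Median centring moves every gene by the same 0.161, so the median of -0.90 after it speaks only against a uniform offset of the libraries. With quantile normalization, which does not move all genes alike, the median was -0.91. Handling of the hearts before extraction may have differed between the groups, since these genes respond to it and the heat shock list had a median of -0.28. Handling and genotype cannot be told apart, because no label gives the order or time of collection. An effect of Tbx20 overexpression stays among the open explanations, untested.

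Hba-a1 and Snord33 were called higher. For Hba-a1 the joining of different gene copies in the series-wide table is a candidate cause, since with values joined by locus the log2 fold change was 4.26 instead of 7.45 and the adjusted p 0.848, as control replicate 2 then held 106 FPKM and the control libraries lay far apart. For Snord33 unstable estimates of very short genes are a candidate cause, since 52.6% of the 19 tested snoRNA genes were at 0 in one library of a group and at 10 FPKM or more in the other. Both libraries of each group were alike for Snord33 itself, so a difference in its level stays open, though the authors' deposited comparison did not call it (cuffdiff q = 0.906).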
